A study of Mus musculus with 9 samples.

How the data were processed

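Gene expression was measured by RNA-seq in mouse sublingual salivary glands, the pair of mucous salivary glands under the tongue, from wild-type animals. The 9 libraries fall into 3 groups of 3: glands that were not irradiated, glands taken 7 days after irradiation and glands taken 14 days after irradiation with 10 Gy. Per the labels' protocols, RNA was isolated from tissue sections of each gland and treated with DNase. Each library was deposited as a table of whole-number counts per gene, 54532 genes in all, with no normalisation. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the mm10 build. Their versions and settings, the annotation, and whether reads were counted by strand are not given in the sources used here.

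Gene identifiers were matched to symbols and gene models of GENCODE M21, and 54409 of the 54532 identifiers matched a symbol. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names, counted from 1. Total counts per library ran from 15962399 to 19441239, and a count of 3 in a library corresponded to between 0.154 and 0.188 CPM, the count scaled to a common library total. Intervals made from counts cover counting error only, since reads amplified by PCR are not independent molecules. No pair of libraries within a group differed by as little as sampling noise (chi-square per degree of freedom 9.927 to 137.595), so all 9 counted as separate samples. The labels number the replicates and do not state that they come from separate animals, so p-values measure the spread between these samples, which may be partly technical.

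Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (15348 tested, 39184 removed), libraries were scaled by TMM, and the quasi-likelihood F test (two-sided, robust, 6 residual degrees of freedom) was run on a design of 3 groups in which all 9 libraries shared an estimate of the spread. The Benjamini-Hochberg adjusted p threshold was 0.05 within each comparison, and an adjusted p of a gene below comes from this test on all 9 libraries unless another tool or setting is named. Changes are log2 fold changes with standard errors (SE), and group values are TMM-scaled CPM, mean ± SD of 3 libraries. The biological coefficient of variation was 16.1%. On counts simulated for the comparison of day 7 with control, with 200 genes changed (15066 genes tested), edgeR recovered 26.9% of the genes changed 1.5-fold, 52.2% of those changed 2-fold and 81.8% of those changed 4-fold, with 8 false calls (7% of calls).

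Before the data were examined, 35 gene lists for cell types, pathways and complexes of the gland and of the radiation response were fixed, together with the tests, the alternatives and the rule for named genes. The 32 lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were run as alternatives. On the simulated counts camera called only the raised list (adjusted p = 0.00653). Correlation as high as in the real lists (0.748 for ribosomal protein at day 7) was not tested there. The neutrophil, B cell and mast cell lists had 2 tested members each and were not tested as sets. Some lists share members, so their results are not independent.

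Named genes were those with the largest change, 6 up and 6 down per comparison, among genes past the threshold with a mean of at least 5 CPM, no overlap between the groups' libraries and a symbol that is not a predicted name. To these were added up to 4 members with the smallest p of each list described and 20 genes of salivary, radiation, nerve, stromal and immune interest given whatever their result. The acinar list was chosen for description at day 7 after its result was seen. Other members of the lists are named where 5 or fewer were called in a direction, and the text says that these were chosen after their values were seen. The same holds for Mucl2, Prol1 and 3 further gene lists, for Atf4 targets, sterol synthesis and resident lymphocytes and dendritic cells, with the 6 members of smallest p of each. Some genes that these rules take are counted but not reported by name here. Of 214 genes taken, 78 overlap a gene on the other strand, and without strand their reads cannot be told apart from those of that gene. Counts of Dcpp1, Dcpp2 and Dcpp3, of the Klk1b kallikreins, of H2 genes, of haemoglobin genes and of immunoglobulin variable genes are uncertain where reads were split between near-identical copies.

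Alternatives were DESeq2 size factors, a scaling without the 20 most abundant genes, no filter on low counts, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test, and the likelihood-ratio test for a difference among all groups), limma-voom with sample weights, only the 6 libraries compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. A correction of each library for a smooth trend of log2 CPM on exonic length and GC content (natural splines with 5 degrees of freedom, as offsets) was chosen after seeing the data, as were a version of it whose trend was fitted outside the ribosomal protein and oxidative phosphorylation lists and a closer look at the fit without control library 3. In simulated counts of day 7 against control with an added length trend (14996 genes tested), it brought the false calls from 1401 to 4. Because both times after irradiation were compared with the same 3 controls, unchanged groups with shared controls were simulated 30 times.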

Results

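The 9 sublingual gland libraries of wild-type mice were 3 controls, 3 taken 7 days after irradiation with 10 Gy and 3 taken 14 days after it. Acini of this gland secrete mostly mucus, and the series concerns regeneration of salivary glands damaged by radiation. The filter on low counts left 15348 genes.

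Secretory transcripts were among the most abundant. A2ml1, Dcpp2, Dcpp3, Muc19 and Dcpp1 were the most abundant genes, and the 20 most abundant genes held 37.8 ± 0.765% of counts in controls, 31.6 ± 0.520% at day 7 and 33.7 ± 0.831% at day 14 (mean ± SD, n = 3). A2ml1 held 6.19 ± 0.695% of counts in controls and 9.65 ± 0.361% at day 7, while Dcpp2 held 8.18 ± 1.54% and 5.48 ± 0.232%. The first principal component of log2 CPM held 31.9% of the variance and placed the 3 day 7 libraries apart from the controls, with day 14 between them. Control library 3 stood apart on the third component, at −41.56, where the other libraries lay between −7.6 and 25.32. Spearman correlations were 0.981 to 0.990 within groups and 0.959 to 0.984 between groups.

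Fold changes moved with the length of the gene. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold change with exonic length was 0.423 at day 7 against control, 0.336 at day 14 against control and −0.283 at day 14 against day 7. The median log2 change at day 7 went from −0.372 in the decile of the shortest genes to 0.379 in that of the longest. Each comparison was therefore repeated after correcting every library for length and GC content, an alternative chosen after seeing the data.

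**Figure D1:**
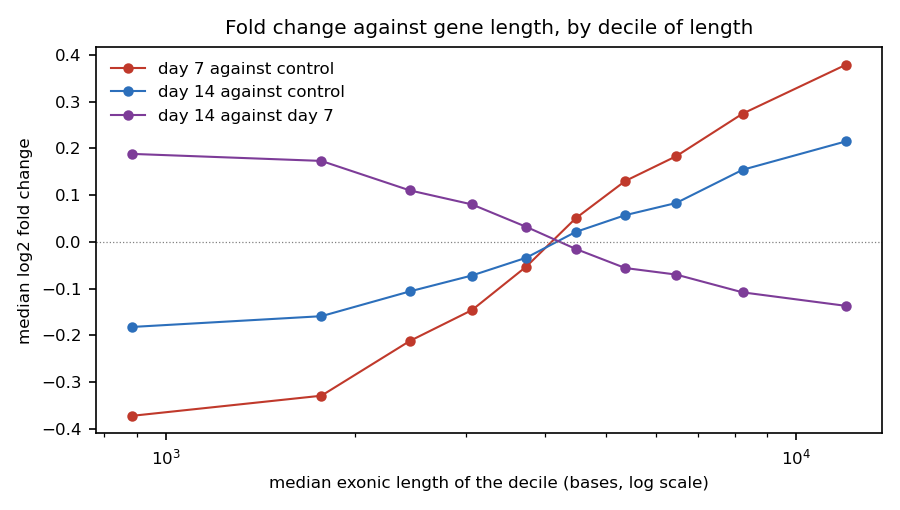
Median log2 fold change of the genes in each decile of exonic length (y axis) against the median length of the decile in bases (x axis, log scale), for the 3 comparisons. The day 7 line climbs from −0.372 to 0.379, the day 14 line from −0.182 to 0.215, and the line of day 14 against day 7 runs the other way, from 0.188 to −0.137.

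The comparison of day 7 with control asks which transcripts differ in the gland in the days after irradiation. At day 7, 25 of 30 cell cycle genes and 11 of 29 p53 targets rose, while 11 of 16 antigen presentation genes, all 30 ribosomal protein genes and 22 of 28 nuclear genes of the respiratory chain fell. As sets these lists passed with the preset correlation and not with an estimated one (adjusted p = 0.151, 0.0906, 0.151, 0.258 and 0.363). Mki67, which encodes the proliferation antigen Ki-67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), rose from 2.79 ± 0.853 to 32.1 ± 6.76 CPM, 11.4-fold (log2 3.52, SE 0.353, adjusted p = 7.31e-05). H2-Ab1, an MHC class II chain (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), fell from 92.4 ± 3.90 to 31.2 ± 5.17 CPM (log2 −1.57, SE 0.114, adjusted p = 9.28e-08). In all, 4692 genes passed the threshold, 2419 higher and 2273 lower (51.6% higher). After the length and GC correction 3330 passed, 34.9% of them higher, and 53.1% of the first set remained.

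Of 30 cell cycle genes, 25 rose at day 7 and 5 did not pass, and 28 rose when adjusted over the list alone. Their median log2 change was 2.45 (camera adjusted p = 3.82e-20; adjusted p = 0.151 with an estimated correlation). Besides Mki67, the genes with the largest changes included Top2a, the topoisomerase of dividing cells (log2 3.56, SE 0.620), Racgap1, needed for cytokinesis (3.25, SE 0.346), the cyclin Ccna2 (2.73, SE 0.334) and Cdc20, an activator of the anaphase-promoting complex (2.63, SE 0.284). The mitotic genes Tpx2 and Kif23 rose by log2 2.96 (SE 0.351) and 3.16 (SE 0.402). Of 25 DNA repair genes, 5 rose and 20 did not pass, with the same counts when adjusted over the list alone. With control library 2 left out 8 rose, and the median was 0.245 after the length correction. The DNA repair list had a median log2 change of 0.386 (camera adjusted p = 0.00275; adjusted p = 0.151 with an estimated correlation). Among them were the damage kinases Atm (1.18, SE 0.230) and Atr (0.82, SE 0.174), the mismatch repair gene Msh6 (0.65, SE 0.144) and Fancd2 (2.15, SE 0.508).

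Of 29 tested p53 targets, 11 rose, 1 fell and 17 did not pass (12 and 1 when adjusted over the list alone). The p53 list had a median log2 change of 0.292 (camera adjusted p = 0.000113; adjusted p = 0.0906 with an estimated correlation). After the length correction the median was 0.473 and the list also passed with an estimated correlation (adjusted p = 0.0115). Cdkn1a, the cyclin-dependent kinase inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose from 5.67 ± 0.351 to 13.9 ± 1.04 CPM (log2 1.30, SE 0.176, adjusted p = 4.88e-05). The receptor gene Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216) rose 3.86-fold (log2 1.95, SE 0.209). Ephx1, an epoxide hydrolase, and the cyclin Ccng1 rose by log2 1.34 (SE 0.091) and 1.02 (SE 0.117). The member that fell was Rps27l (−0.36, SE 0.103), named after its value was seen, a call lost without control library 1 or day 7 library 1 and after the length correction (−0.27). Without control library 3, 3 fell. The key gene Mdm2 did not pass (0.29, SE 0.114, adjusted p = 0.0595).

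Antigen presentation genes fell in 11 of 16 cases, with the same count when adjusted over the list alone, and 5 did not pass. The antigen presentation list had a median log2 change of −0.598 (camera adjusted p = 9.23e-12; adjusted p = 0.151 with an estimated correlation). Cd74, the invariant chain of MHC class II, fell by 1.41 on the log2 scale (SE 0.104), H2-Eb1 by 1.54 (SE 0.114) and H2-Aa by 1.5 (SE 0.115). All 30 cytosolic ribosomal protein genes fell, also when adjusted over the list alone. The ribosomal list had a median log2 change of −0.658 (camera adjusted p = 1.46e-23; adjusted p = 0.258 with an estimated correlation). Among them were Rps14 (−0.81, SE 0.095), Rpl8 (−0.71, SE 0.086), Rpsa (−0.69, SE 0.085) and Rps23 (−0.75, SE 0.094). Of 28 nuclear genes of oxidative phosphorylation, 22 fell and 6 did not pass (1 rose and 23 fell when adjusted over the list alone). The oxidative phosphorylation list had a median log2 change of −0.548 (camera adjusted p = 4.45e-12; adjusted p = 0.363 with an estimated correlation). Ndufb8 (−0.79, SE 0.110), Cox7a2 (−0.78, SE 0.112), Cyc1 (−0.63, SE 0.099) and Atp5h (−0.57, SE 0.092) were among them. These are mostly short genes, and after the length and GC correction the medians of the ribosomal and oxidative phosphorylation lists were −0.463 and −0.390, with 29 and 18 members lower.

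Among secretory genes, 3 of 22 acinar genes rose, 9 fell and 10 did not pass (4 and 11 when adjusted over the list alone), and the list did not pass as a set (median log2 −0.374, camera adjusted p = 0.144), except without control library 3 (adjusted p = 0.0493). The salivary demilune and parotid protein genes Dcpp1 (ENSMUSG00000096445, chromosome 17, 23880876 to 23882853) and Dcpp2, near-identical copies whose counts are uncertain, fell by 0.76 (SE 0.110) and 0.78 (SE 0.111). Muc19, a major gel-forming mucin of the gland (ENSMUSG00000044021, chromosome 15, 91838326 to 91934555, annotated as a processed transcript), fell from 42783 ± 4068 to 32956 ± 2504 CPM (log2 −0.38, SE 0.092, adjusted p = 0.00479). Spdef, a transcription factor of mucous cells, fell by 0.62 (SE 0.117) and Bhlha15, a transcription factor of acinar cells, by 0.46 (SE 0.095). The members that rose were the chloride channel Ano1 (0.78, SE 0.103), the chloride cotransporter Slc12a2 (0.69, SE 0.167) and Gcnt3 (0.61, SE 0.166), the last pair named after their values were seen.

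Of 20 genes of muscarinic signalling and ion transport, 9 rose, 2 fell and 9 did not pass (12 and 2 when adjusted over the list alone). The muscarinic list had a median log2 change of 0.325 (camera adjusted p = 0.00183; adjusted p = 0.151 with an estimated correlation). After the length correction 4 rose, neither fall was called and the median was 0.182. The inositol trisphosphate receptors Itpr3 (0.84, SE 0.103) and Itpr1 (0.65, SE 0.151) and the sodium pump subunit Atp1b1 (0.51, SE 0.112) rose. The calcium channel Orai1, named after its value was seen, fell by 0.55 (SE 0.142), and the water channel Aqp5 fell by 0.27 (SE 0.1, adjusted p = 0.044), to −0.043 after the length correction. Without control library 1 or 2, day 7 library 1, 2 or 3 or day 14 library 1 or 3 Aqp5 was not called and 1 of the list fell. Neither receptor of acetylcholine passed (Chrm1 0.32, SE 0.123; Chrm3 −0.01, SE 0.093). Of 24 genes of the unfolded protein response, 1 rose and 7 fell (1 and 9 when adjusted over the list alone). The unfolded protein response list had a median log2 change of −0.259 (camera adjusted p = 0.000675; adjusted p = 0.674 with an estimated correlation). The ER chaperone gene Calr fell by 0.68 (SE 0.094), Creld2 by 0.95 (SE 0.106), Manf by 0.99 (SE 0.112) and Sdf2l1 by 0.91 (SE 0.145), whereas Sel1l, named after its value was seen, rose by 0.44 (SE 0.142), a call lost without control library 1 or 2 or day 7 library 1 or 2 and after the length correction (0.17). With the length correction 11 of the list fell.

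Circadian clock genes moved in opposite directions at day 7. Of 16, 9 rose, 3 fell and 4 did not pass, with the same counts when adjusted over the list alone. The clock list had a median log2 change of 0.815 (camera adjusted p = 0.00275; adjusted p = 0.261 with an estimated correlation). Arntl, the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), fell from 12.4 ± 0.767 to 1.05 ± 0.208 CPM (log2 −3.55, SE 0.227, adjusted p = 3.25e-08). Nfil3 and Npas2 were the others that fell (−2.47, SE 0.298; −2.20, SE 0.380), the second named after its value was seen. Per3 rose 6.39-fold (log2 2.68, SE 0.332), and the clock output genes Dbp and Tef rose by 1.62 (SE 0.131) and 1.31 (SE 0.131). The collection times are not given in the sources used here.

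**Figure D2:**
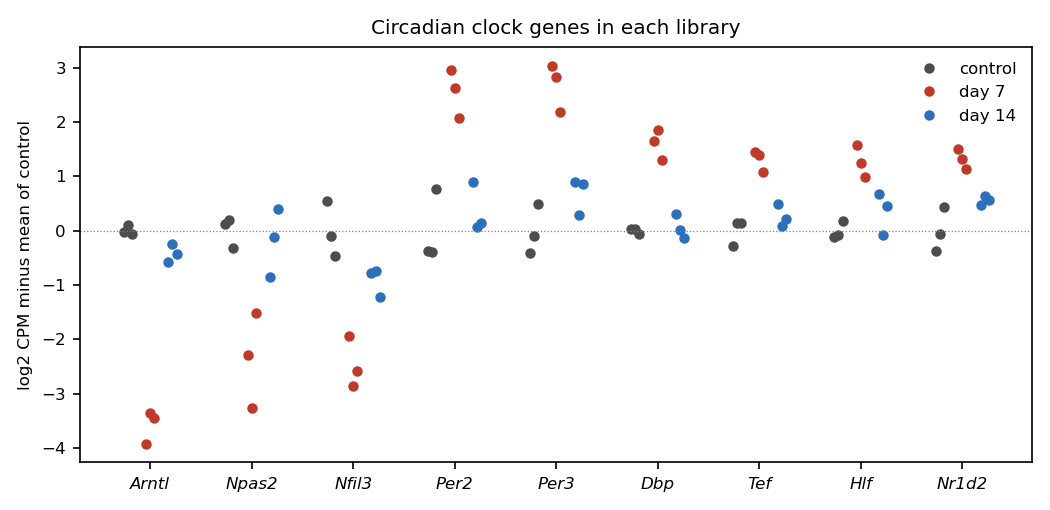
Log2 CPM minus the mean of the controls (y axis) for 9 clock genes (x axis), with a point per library, 3 for each of control, day 7 and day 14. For Arntl, Npas2 and Nfil3 every day 7 point lies below every control point, and for Per2, Per3, Dbp, Tef, Hlf and Nr1d2 every day 7 point lies above.

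Matrix genes rose in 9 of 28 cases and fell in 1, with the same counts when adjusted over the list alone. The matrix list had a median log2 change of 0.185 (camera adjusted p = 0.0459; adjusted p = 0.680 with an estimated correlation). The collagen genes Col1a1 (0.62, SE 0.12), Col1a2 (0.59, SE 0.103) and Col5a1 (0.58, SE 0.160) and the matrix protein gene Postn (0.68, SE 0.164) rose, while Tgfb1, named after its value was seen, fell by 0.41 (SE 0.141), a call lost without control library 1 or 2 or day 7 library 2 or 3 (−0.50 to −0.28 over all omissions). In the fits without control library 2 and day 7 library 1 the matrix genes that rose were 4 and 5. This list call ended without control library 2 or 3, day 7 library 1 or 3, or day 14 library 2 (median 0.071 to 0.313 over all omissions, highest adjusted p = 0.168) and after the length correction (adjusted p = 0.152; 4 rose and 2 fell). Of 14 plasma cell genes, 3 fell, also when adjusted over the list alone. The plasma cell list had a median log2 change of −0.908 (camera adjusted p = 0.0169; adjusted p = 0.674 with an estimated correlation). The 3 genes were Derl3 (−0.59, SE 0.122), the immunoglobulin gene Ighm (−1.22, SE 0.350) and Mzb1 (−1.21, SE 0.424), and 1 fell without day 7 library 2. That call ended without control library 3 (median −0.524) and after the length correction (adjusted p = 0.0965; 1 fell).

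Of 15 genes of the submandibular granular duct, a duct type of the neighbouring gland, 3 fell and 12 did not pass (1 fell when adjusted over the list alone). The submandibular list had a median log2 change of −1.14 (camera adjusted p = 0.0157; adjusted p = 0.698 with an estimated correlation). The 3 genes were the kallikreins Klk1b9 (−1.08, SE 0.260), Klk1b8 (−1.48, SE 0.535) and Klk1b24 (−0.90, SE 0.331), whose counts are uncertain because their sequences are near-identical. The list mean lay at 1.25 on the log2 scale in control library 3 and at −0.542 and −0.710 in the other controls, relative to the control mean. In the fits without day 7 library 1, 2 or 3 only 1 member fell. The call ended without control library 3 (median −0.432), without day 7 library 3 and after the length correction, where the 3 calls were lost (adjusted p = 0.154). The largest falls at day 7 also included the secretoglobins Scgb1b27 (−2.96, SE 0.731) and Scgb2b27 (−1.87, SE 0.324) and Retnla, a product of alternatively activated macrophages (−2.54, SE 0.378). The immunoglobulin segment Igkv17-121 had 1 count over the day 7 libraries against 942 over the controls, a ratio of 1060 (exact 95% interval 190 to 42100, counting error only). Of the control counts 12, 258 and 672 were in libraries 1, 2 and 3, and without control library 3 the ratio was 478 (exact 95% interval 85 to 18900).

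The other 20 lists tested did not pass at day 7 (camera adjusted p 0.0959 to 0.983). Exceptions were the basal list after the length correction (adjusted p = 0.047; adjusted p = 0.543 with an estimated correlation), the ductal list without control library 1 (0.0496) or day 7 library 2 (0.0372) and the mitochondrially encoded list without day 7 library 3 (0.0277). Called members of these lists were named after their values were seen except for the key genes. Of 20 ductal genes Egf, Scnn1a and Kit rose and 7 fell. Of 20 macrophage genes Mertk rose and the complement genes C1qa, C1qb and C1qc fell. Of 13 mitochondrially encoded genes mt-Nd5 rose and 7 fell. Of 30 type I interferon genes Ifih1 and Trim30a rose and Bst2 fell. Of 9 pericyte genes Myh11, Notch3 and Cspg4 rose and Des fell, which was also the only skeletal muscle gene of 7 to pass. Of 17 immediate early genes Egr1 rose and Jund, Ier2, Ier3 and Zfp36 fell. Of 13 epithelial progenitor genes Sox2 and Kit rose and Sox10, Ascl3 and Cd24a fell. With day 7 library 1 left out 4 ductal genes fell, and 4 and 3 mitochondrially encoded genes fell without control library 2 and day 7 library 2. Without control library 3, 4 interferon, 3 endothelial, 2 senescence and 2 immediate early genes rose and 2 adipocyte genes fell. With day 7 library 3 left out, 4 signalling and 3 immediate early genes rose. Of macrophage genes 2 rose without day 7 library 2 or day 14 library 2 or 3, and 5 fell without day 14 library 3. With the length correction 2 senescence genes rose.

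Of 17 neurotrophic genes Nrg1, Sema3c and Sema3a rose and Nrtn fell. Of 15 Schwann cell genes Erbb3 and Cdh19 rose and Sox10 and Cnp fell. Of 13 senescence genes Cdkn1a rose and Plaur fell, and of 7 adipocyte genes Plin4 rose and Lpl fell. Itgb4, Myh11 and Col17a1 rose among 11 basal and myoepithelial genes, Vwf and Tek among 18 endothelial genes, and Notch1 and Fgfr2 among 22 genes of Wnt, Hedgehog, Fgf and Notch signalling. By edgeR 0 genes passed in the neuronal, T and NK cell, lymphatic endothelial and erythrocyte lists. There 0, 3, 0 and 0 had an unadjusted p under 0.05, DESeq2 called 0, and limma-voom called 2, both in the T and NK cell list. Of the lists with 2 tested members, 1 mast cell gene (Kit) rose, and neutrophil and B cell genes did not pass by edgeR or DESeq2. Of the B cell genes 1 had an unadjusted p under 0.05 and was called by limma-voom. Median, mean and test differed in sign for the Schwann cell (median 0.045, mean −0.034, test down), neurotrophic (−0.085, −0.196, up), senescence (−0.055, 0.075, up) and epithelial progenitor (0.092, 0.005, down) lists.

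Nerve-related key genes gave mixed results at day 7. Nrtn, a ligand that supports parasympathetic neurons, fell by 0.49 (SE 0.138, adjusted p = 0.0121) and Sox10, a factor of Schwann cells and of gland epithelium, by 0.46 (SE 0.097, adjusted p = 0.00165), to −0.21 and −0.27 after the length correction, where neither passed. Sox2, a progenitor factor, rose by 0.34 (SE 0.101, adjusted p = 0.0148). Tubb3 (−0.89, SE 1.54), Vip (−0.63, SE 1.00), Krt19 (−0.53, SE 0.277), Krt5 (−0.17, SE 0.112), Adgre1 (−0.07, SE 0.222), Isg15 (−0.39, SE 0.406) and Pecam1 (0.15, SE 0.133) did not pass. Of the genes called at day 7, 4459 had no overlap between the groups' libraries, as did 43.9% of the genes tested, where chance gives 10%. Without day 7 library 1 the number of called genes was 3106, and of 120 named genes called at day 7, 85 passed with each library left out in turn.

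Of the genes named above as called at day 7, Aqp5, Ascl3, Atr, Bst2, C1qa, C1qb, Cdh19, Cnp, Cspg4, Derl3, Des, Egf, Fgfr2, Ier2, Ier3, Ighm, Igkv17-121, Kit, Klk1b24, Klk1b8, Klk1b9, Mzb1, Notch3, Nrg1, Nrtn, Orai1, Postn, Rps27l, Sel1l, Sema3a, Sema3c, Slc12a2, Sox10, Tek, Trim30a, Vwf and Zfp36 no longer passed after the length correction (highest adjusted p = 0.81, for Aqp5). The Sema3a call ended in each omission but that of day 14 library 3, the Igkv17-121 call in each but those of control library 1 and day 14 library 2, and those of Cd24a, Cspg4 and Klk1b24 without control library 1 or 2 or any day 7 library (Cspg4 also without day 14 library 2). Calls not covered so far ended without control library 1 for Cdh19, Cnp, Col17a1, Des, Gcnt3, Kit, Nrtn, Plaur, Plin4, Scnn1a, Sox2, Trim30a and Zfp36, without control library 2 for Cdh19, Cnp, Col17a1, Des, Kit, Notch3, Plin4, Scgb1b27, Tek, Trim30a, Vwf and Zfp36 and without control library 3 for Ascl3, Des, Ighm, Klk1b8, Mzb1, Notch3, Scgb1b27 and Tek. With day 7 library 1 left out those of Ascl3, Cnp, Col17a1, Des, Ighm, Kit, Klk1b8, Notch3, Plin4, Scgb1b27, Tek and Vwf ended, with library 2 those of Gcnt3, Ighm, Kit, Klk1b8, Mzb1, Notch3, Scnn1a, Tek and Zfp36, and with library 3 those of Ascl3, Cdh19, Cnp, Des, Ier3, Klk1b8, Mzb1, Plin4, Scgb1b27, Sox2, Trim30a and Zfp36. That of Klk1b8 also ended without day 14 library 1. The highest adjusted p in these fits was 0.421 (Klk1b8).

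**Figure D3:**
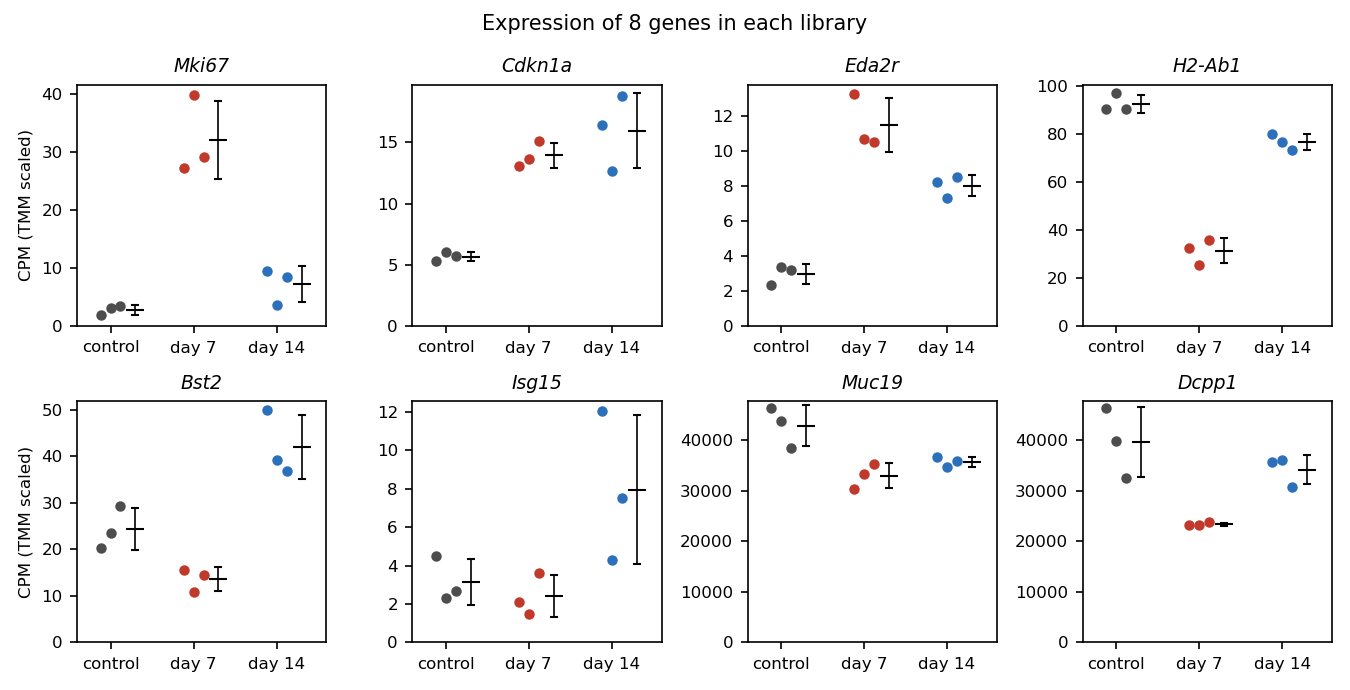
CPM, scaled by TMM (y axis, from 0), of 8 genes in each library of control, day 7 and day 14 (x axis), with a point per library and the mean ± SD of 3 libraries beside them. Mki67 lies between 27.2 and 39.8 at day 7 against 1.83 to 3.45 in controls, and H2-Ab1 between 25.5 and 35.6 against 90.1 to 96.9.

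The comparison of day 14 with control asks which differences are present later. At day 14, 4 of 29 p53 targets, 5 of 30 type I interferon genes and 3 of 20 macrophage genes rose against control, and 2 of 30 ribosomal protein, 1 of 28 respiratory chain and 2 of 20 ductal genes fell. As sets these lists passed with the preset correlation and not with an estimated one (adjusted p = 0.12, 0.391, 0.391, 0.440, 0.440 and 0.391). Cdkn1a rose from 5.67 ± 0.351 to 16.0 ± 3.08 CPM, 2.81-fold (log2 1.49, SE 0.175, adjusted p = 0.000905), and Eda2r rose 2.70-fold (log2 1.43, SE 0.210, adjusted p = 0.0048). Fewer genes passed than at day 7: 270, of which 173 were higher and 97 lower (64.1% higher). After the length and GC correction 142 passed, 42.3% of them higher, and 30% of the first set remained.

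Of 30 type I interferon response genes, 5 rose and 25 did not pass, and 24 rose when adjusted over the list alone. The interferon list had a median log2 change of 1.10 (camera adjusted p = 6.18e-18; adjusted p = 0.391 with an estimated correlation). DESeq2 called 17 and limma-voom 12. The RNA sensor Ifih1 (0.89, SE 0.157), Trim30a (1.71, SE 0.317), the tetherin gene Bst2 (ENSMUSG00000046718, chromosome 8, 71534255 to 71537456; 0.78, SE 0.160), the nucleotide kinase Cmpk2 (1.33, SE 0.316) and the nucleic acid sensor Zbp1 (1.16, SE 0.278) rose. Isg15 did not pass (1.33, SE 0.389, adjusted p = 0.0773). The list mean differed between the day 14 libraries, at 1.56, 0.447 and 1.10 above the control mean. Of 20 macrophage and monocyte genes, 3 rose and 17 did not pass (10 rose when adjusted over the list alone). The macrophage list had a median log2 change of 0.514 (camera adjusted p = 2.57e-07; adjusted p = 0.391 with an estimated correlation). The 3 genes were Ms4a7 (1.31, SE 0.247), the mannose receptor Mrc1 (1.07, SE 0.226) and the engulfment receptor Mertk (0.47, SE 0.109). Adgre1, which encodes the macrophage antigen F4/80, did not pass (0.51, SE 0.219).

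Of 29 p53 targets, 4 rose, 1 fell and 24 did not pass (7 and 2 when adjusted over the list alone). The p53 list had a median log2 change of 0.320 (camera adjusted p = 0.000231; adjusted p = 0.12 with an estimated correlation). With the length correction it also passed with an estimated correlation (adjusted p = 0.0187). Ephx1 (0.65, SE 0.090) and Ccng1 (0.80, SE 0.117) rose with Cdkn1a and Eda2r, and Sesn2, a stress-induced regulator of growth, fell by 1.55 (SE 0.261), a call that ended after the length correction. Of 28 matrix genes, Postn rose (0.75, SE 0.164; 0.35 and not called after the length correction) and 27 did not pass (9 rose when adjusted over the list alone). The matrix list had a median log2 change of 0.328 (camera adjusted p = 2.93e-05; adjusted p = 0.391 with an estimated correlation). Col1a1 did not pass (0.36, SE 0.12). No cell cycle gene passed in edgeR (0 of 30; 7 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0), although the list passed as a set (median 0.454, camera adjusted p = 0.00169; adjusted p = 0.552 with an estimated correlation). That call ended without day 14 library 1 (adjusted p = 0.0519, median 0.257). Mki67 did not pass (1.35, SE 0.361, adjusted p = 0.0762).

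Ribosomal protein genes were called lower in 2 of 30 cases, Rpl32 (−0.38, SE 0.088) and Rps18 (−0.39, SE 0.096), and in 29 when adjusted over the list alone. Both calls ended after the length correction (−0.23 and −0.31). The ribosomal list had a median log2 change of −0.299 (camera adjusted p = 8.97e-14; adjusted p = 0.440 with an estimated correlation). Of 28 oxidative phosphorylation genes, Cox7a2 fell (−0.50, SE 0.111; −0.34 and not called after the length correction), and 17 fell when adjusted over the list alone. The oxidative phosphorylation list had a median log2 change of −0.265 (camera adjusted p = 6.37e-11; adjusted p = 0.440 with an estimated correlation). The mitochondrially encoded list passed as lower and had a median log2 change of −0.305 (camera adjusted p = 0.0135; adjusted p = 0.552 with an estimated correlation). The member that passed of its 13, mt-Nd5, rose (0.51, SE 0.110; 1 rose and 4 fell when adjusted over the list alone), and after the length correction 2 members fell and it was not called. Of 20 ductal genes, Wfdc2 (−0.71, SE 0.124) and the kallikrein Klk1 (−0.98, SE 0.189) fell and 18 did not pass (5 fell when adjusted over the list alone, and 1 over all genes after the length correction). The ductal list had a median log2 change of −0.239 (camera adjusted p = 3.82e-05; adjusted p = 0.391 with an estimated correlation).

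Other lists passed with no called member in edgeR. In the unfolded protein response list 0 of 24 genes passed (1 higher and 9 lower had an unadjusted p under 0.05, DESeq2 called 6 lower and limma-voom 1 each way; 1 rose and 6 fell when adjusted over the list alone), with a median log2 of −0.177 (camera adjusted p = 0.000931; adjusted p = 0.552 with an estimated correlation). Its members with the smallest p were Trib3 (−2.21, SE 0.472), Manf (−0.35, SE 0.110), Chac1 (−2.66, SE 0.627) and Atf4 (−0.39, SE 0.122). The call ended without day 14 library 3 (adjusted p = 0.0767; medians −0.284 to −0.126 over all omissions). In the submandibular list 0 of 15 passed (4 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0; median −0.832, camera adjusted p = 0.00116; adjusted p = 0.552 with an estimated correlation). Without control library 3 the median was 0.033 and the call ended. In the erythrocyte list 0 of 5 passed by edgeR, DESeq2, limma-voom or an unadjusted p under 0.05 (median −1.52, camera adjusted p = 0.0165; adjusted p = 0.552 with an estimated correlation). That call ended without control library 2 (which had the highest list mean, 1.31), without day 14 library 1 (medians −0.545 to −1.89 over all omissions) and after the length correction (adjusted p = 0.0566).

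The genes with the largest changes at day 14 also included the motor protein Myo5a (1.19, SE 0.294), which rose. The largest falls included Cst10 (−1.22, SE 0.211), the potassium channel Kcnk3 (−1.11, SE 0.225), the ATP synthase subunit Atp5k (−1.02, SE 0.236) and the hormone gene Adm2 (−0.97, SE 0.169). Myo5a, Atp5k and Adm2 were not called after the length correction (adjusted p = 0.0576, 0.113 and 0.0669). The acinar key genes did not pass: Muc19 lay at 35703 ± 1007 CPM (log2 −0.26, SE 0.092, adjusted p = 0.114), with Dcpp1 at −0.21 (SE 0.109), Aqp5 at −0.17 (SE 0.1) and Bhlha15 at −0.20 (SE 0.095). Chrm1 (0.01, SE 0.124), Chrm3 (−0.02, SE 0.093), Mdm2 (−0.02, SE 0.114), Krt19 (−0.65, SE 0.279), Krt5 (−0.25, SE 0.113), Nrtn (−0.24, SE 0.137), Sox2 (0.20, SE 0.101), Sox10 (−0.19, SE 0.097) and Pecam1 (0.06, SE 0.134) did not pass either. The neuronal genes Tubb3 (−2.95, SE 1.80) and Vip (−4.88, SE 1.41, adjusted p = 0.110) had wide errors, and Vip had 26, 15 and 136 counts in control libraries 1, 2 and 3 and 6 over the day 14 libraries. Tubb3 had 7, 0 and 91 counts in the controls.

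The other 20 lists did not pass at day 14 (camera adjusted p 0.0889 to 0.779). After the length correction the antigen presentation (median 0.273, adjusted p = 0.00043) and senescence (median 0.167, adjusted p = 0.000627) lists passed as higher, neither of them with an estimated correlation (adjusted p = 0.405 and 0.125). The adipocyte list passed as higher without library 1 or 2 of any group (adjusted p at most 0.0357). The neuronal list mean was 1.42 in control library 3 and −0.792 and −0.631 in the other controls. That list passed as lower without control library 1 or 2, day 7 library 3 or day 14 library 3 (at most 0.0373). The senescence list passed as higher without control library 1 or day 14 library 2 or 3 (at most 0.042). The acinar list passed as lower without control library 3 (0.0348) or day 14 library 2 (0.0081), as did the plasma cell list without control library 1 (0.0419) and the endothelial list without day 14 library 3 (0.0166), and the antigen presentation list passed as higher without day 14 library 2 (0.0306). Members that passed in them were Cdkn1a and the protease Mmp12 in the senescence list, Atm and Atr in DNA repair, Sema3c in the neurotrophic list, B2m in antigen presentation and Lpl in the adipocyte list, which rose, though Atr, Sema3c and Lpl not after the length correction. Derl3 in the plasma cell list and Cry2 in the clock list fell. Except for Cdkn1a these members were named after their values were seen. By edgeR 0 genes passed in the acinar, basal, muscarinic, neuronal, Schwann cell, T and NK cell, endothelial, lymphatic endothelial, pericyte, skeletal muscle, immediate early, Wnt, epithelial progenitor, neutrophil, B cell and mast cell lists. At an unadjusted p under 0.05 there were 2 higher and 4 lower acinar, 3 and 1 basal, 5 and 0 muscarinic, 0 and 1 neuronal, 2 and 2 Schwann cell, 1 and 1 endothelial, 1 and 1 pericyte, 0 and 2 skeletal muscle, 1 and 1 immediate early, 3 and 2 Wnt and 2 and 2 epithelial progenitor genes, and 0 in the rest. DESeq2 called 3 acinar, 1 basal, 1 muscarinic and 1 epithelial progenitor gene. Limma-voom called 1 higher and 3 lower acinar genes, 3 basal, 2 muscarinic, 1 endothelial, 1 higher and 1 lower pericyte, 1 skeletal muscle and 2 Wnt genes. Median, mean and test differed in sign for the Schwann cell (median 0.073, mean −0.151, test down), pericyte (0.085, −0.133, down), skeletal muscle (0.036, −0.294, down) and epithelial progenitor (0.081, −0.015, down) lists.

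The number of genes called at day 14 depended on single libraries. It was 13 without control library 1, 15 without control library 2, 1937 without control library 3, 71, 36 and 31 without day 14 libraries 1, 2 and 3, and 148 without day 7 library 2, which is in neither group. Counts within lists moved too. Of interferon genes 11 and 8 rose without control library 3 and day 7 library 3. Without control library 3, 29 ribosomal protein, 17 oxidative phosphorylation, 4 ductal and 4 matrix genes were called, and 4 ribosomal protein genes without day 7 library 1. Of 36 named genes called at day 14, Cdkn1a, Eda2r, Ephx1 and Ccng1 passed with each library left out in turn. Of the 270 genes, 269 had no overlap between the groups' libraries, as did 23.1% of the genes tested, where chance gives 10%.

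Of the genes named above as called at day 14, Adm2, Atp5k, Atr, Cmpk2, Cox7a2, Klk1, Lpl, Mertk, Mrc1, mt-Nd5, Myo5a, Postn, Rpl32, Rps18, Sema3c and Sesn2 no longer passed after the length correction (highest adjusted p = 0.359, for Sema3c). Besides the 4 genes that passed in each omission, all those named lost the call without control library 1 except Derl3, Klk1 and Wfdc2, and without control library 2 except Derl3 and Sesn2. Without day 14 library 1 they did so except Adm2, Cst10, Derl3, Ifih1, Kcnk3, Lpl, Mmp12, Sesn2 and Wfdc2, without library 2 except Adm2, Derl3 and Trim30a and without library 3 except Atp5k, Klk1, Mmp12, Mrc1, Postn and Wfdc2. Calls also ended without day 7 library 1 for Klk1 and Sesn2, without library 2 for Atp5k, Klk1, Mertk, Myo5a, Rpl32, Rps18, Sema3c and Sesn2 and without library 3 for Atp5k, Klk1, Mertk, Myo5a, Postn, Rps18 and Sema3c (highest adjusted p = 0.198, for Sema3c). Without control library 3, 2 p53 targets and 2 clock genes fell and 2 antigen presentation and 2 adipocyte genes rose, and 2 adipocyte genes rose without day 14 library 1.

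**Figure D4:**
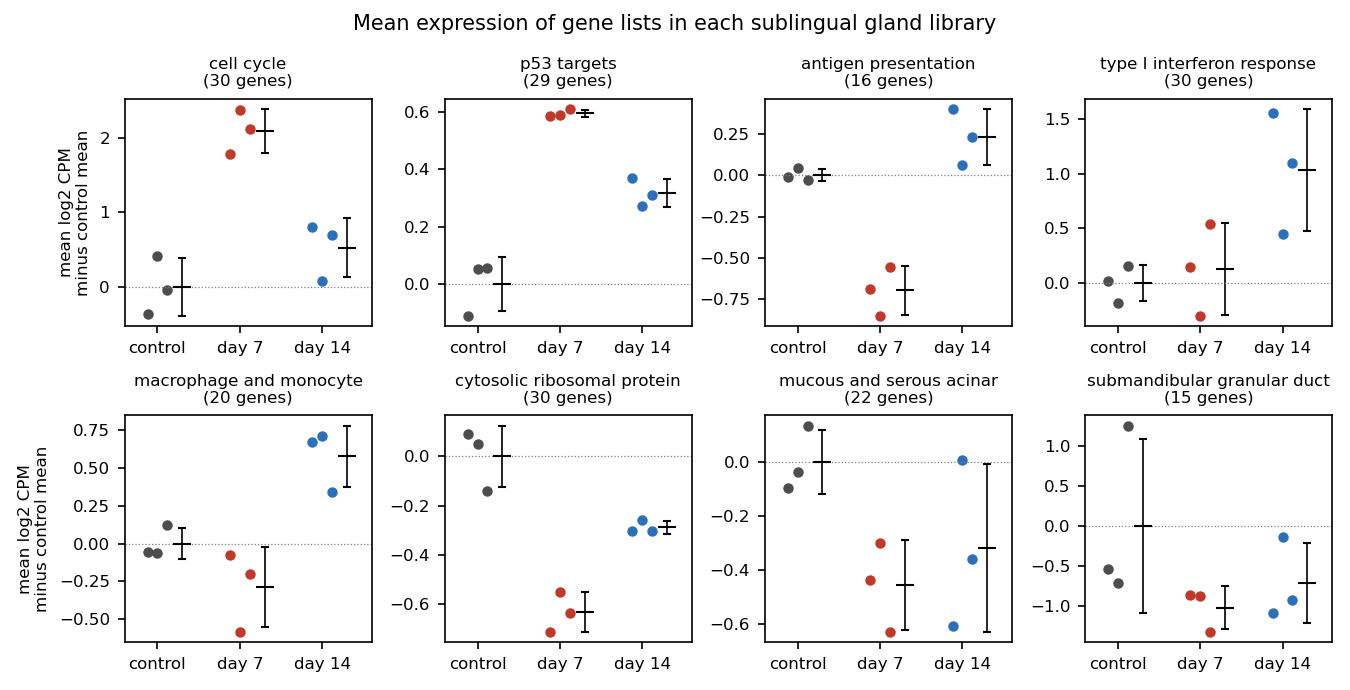
Mean log2 CPM of the tested members of 8 gene lists, minus the mean of the controls (y axis, with its own range in each panel), in each library of control, day 7 and day 14 (x axis), with a point per library and the mean ± SD of 3 libraries beside them. Cell cycle genes lie between 1.78 and 2.37 at day 7 and between 0.070 and 0.806 at day 14, and control library 3 lies at 1.25 in the submandibular list.

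The comparison of day 14 with day 7 tests directly how the effects at the times differ. From day 7 to day 14, 19 of 30 cell cycle genes fell, 12 of 16 antigen presentation, 9 of 20 macrophage and 7 of 30 interferon genes rose, and of 16 clock genes 4 rose and 9 fell. As sets these lists passed with the preset correlation. With an estimated one the antigen presentation list passed (adjusted p = 0.0445) and the cell cycle, macrophage, interferon and clock lists did not (adjusted p = 0.0644, 0.0653, 0.319 and 0.0644). In all, 1011 genes passed, 571 higher at day 14 and 440 lower (56.5% higher), and 927 after the length and GC correction (61.4% higher), with 69% of the first set. Of the 1011 genes, 882 had also passed at day 7 against control, and all 882 moved toward the control level, a direction that the day 7 libraries common to both comparisons favour. Mki67 fell from 32.1 ± 6.76 to 7.16 ± 3.11 CPM (log2 −2.17, SE 0.318, adjusted p = 0.00388), and H2-Ab1 rose from 31.2 ± 5.17 to 76.5 ± 3.25 CPM (log2 1.29, SE 0.113, adjusted p = 3.85e-06).

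Of 30 cell cycle genes, 19 fell and 11 did not pass (26 fell when adjusted over the list alone). The cell cycle list had a median log2 change of −1.74 (camera adjusted p = 1.85e-29; adjusted p = 0.0644 with an estimated correlation). Ccna2 (−2.10, SE 0.317), Prc1 (−2.01, SE 0.259), Cdca3 (−1.95, SE 0.330), Cdc20 (−1.88, SE 0.268) and Birc5 (−2.56, SE 0.418) were among the genes of division that fell. Without day 7 library 2 and day 14 library 2 the cell cycle genes that fell were 8 and 10. Of 25 DNA repair genes, 4 fell (6 when adjusted over the list alone). The DNA repair list had a median log2 change of −0.280 (camera adjusted p = 7.11e-05; adjusted p = 0.0644 with an estimated correlation). Among them were Msh6 (−0.57, SE 0.143), Xrcc6 (−0.46, SE 0.131) and Exo1 (−2.31, SE 0.681), and 1 fell after the length correction. The calls of DNA repair genes were lost without day 7 library 2 or 3 or day 14 library 2, 1 fell without day 7 library 1 or day 14 library 1, and 2 without control library 2 or day 14 library 3. Of 29 p53 targets, Ephx1 (−0.69, SE 0.089), Sesn2 (−1.47, SE 0.260) and Psrc1 (−2.10, SE 0.568) fell (2 rose and 8 fell when adjusted over the list alone). The p53 list had a median log2 change of −0.171 (camera adjusted p = 0.0197; adjusted p = 0.0961 with an estimated correlation). The p53 targets that fell were 1 without day 7 library 1 or day 14 library 2 and 5 without control library 3, and 6 after the length correction. That list call ended without day 7 library 3 or day 14 library 2 (highest adjusted p = 0.0569), and Cdkn1a did not pass (0.20, SE 0.165).

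Antigen presentation genes rose in 12 of 16 cases, in 13 when adjusted over the list alone (median log2 1.11, camera adjusted p = 4.85e-32), and this list alone also passed with an estimated correlation (adjusted p = 0.0445). H2-Eb1 (1.23, SE 0.114), H2-Aa (1.18, SE 0.114) and Cd74 (1.10, SE 0.103) were examples. Of 20 macrophage and monocyte genes, 9 rose and 1 fell (13 and 1 when adjusted over the list alone). The macrophage list had a median log2 change of 0.999 (camera adjusted p = 5.66e-13; adjusted p = 0.0653 with an estimated correlation). The complement genes C1qa (1.09, SE 0.139), C1qb (1.16, SE 0.156) and C1qc (1.18, SE 0.156) and the lysosomal Cd68 (0.93, SE 0.188) rose. Mertk, named after its value was seen, fell by 0.43 (SE 0.107), a call lost without day 7 library 1, 2 or 3 or day 14 library 2 or 3 (−0.49 to −0.39 over all omissions). Without day 7 library 2, 4 macrophage genes rose. Fcrls (1.59, SE 0.217), the chemokine Ccl6 (2.02, SE 0.301) and Retnla (2.37, SE 0.378) were among the largest increases. Of 30 interferon genes, 7 rose (13 when adjusted over the list alone). The interferon list had a median log2 change of 0.902 (camera adjusted p = 5.66e-13; adjusted p = 0.319 with an estimated correlation). Members that rose included Bst2 (1.62, SE 0.165), Isg15 (1.72, SE 0.394), Zbp1 (1.38, SE 0.280) and Oas1a (2.07, SE 0.395). Without day 14 library 1 the interferon median was 0.593 and 2 genes rose. There were 13 without day 14 library 2, and 3 without day 7 library 1 or 2 or day 14 library 3. In the T and NK cell list the adhesion receptor Cd2 rose (2.14, SE 0.597), alone of 10 also when adjusted over the list alone (median 1.17, camera adjusted p = 0.00225; adjusted p = 0.0653 with an estimated correlation). The Cd2 call ended in each fit that left out a library of day 7 or day 14 (1.81 to 2.45 over all omissions). Nkg7, Ncr1 and Klrb1c did not pass (1.28, SE 0.585; 1.46, SE 0.723; 1.22, SE 0.611).

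Of 30 ribosomal protein genes, 22 rose (29 when adjusted over the list alone). The ribosomal list had a median log2 change of 0.345 (camera adjusted p = 9.52e-15; adjusted p = 0.319 with an estimated correlation). Rps14 (0.47, SE 0.095), Rpl8 (0.41, SE 0.086), Rps23 (0.44, SE 0.094) and Rps3 (0.45, SE 0.097) were among them, and 6 rose after the length correction. The count depended on single libraries. It was 3, 9 and 7 without day 7 libraries 1, 2 and 3, 8, 4 and 9 without day 14 libraries 1, 2 and 3, and 10 without control library 2. Of 28 oxidative phosphorylation genes, Ndufb8 (0.47, SE 0.110), Ndufa4 (0.43, SE 0.111), Cox5a (0.36, SE 0.098) and Ndufs3 (0.34, SE 0.102) rose (11 when adjusted over the list alone). The oxidative phosphorylation list had a median log2 change of 0.239 (camera adjusted p = 6.74e-05; adjusted p = 0.565 with an estimated correlation). After the length correction 1 of the list rose and its median was 0.13. Of 16 clock genes, 4 rose and 9 fell (4 and 12 when adjusted over the list alone). The clock list had a median log2 change of −0.835 (camera adjusted p = 5.29e-08; adjusted p = 0.0644 with an estimated correlation). Arntl (3.14, SE 0.227), and, named after their values were seen, Npas2 (2.09, SE 0.379), Nfil3 (1.52, SE 0.297) and Clock (0.71, SE 0.172), rose, while Per2 (−2.19, SE 0.390), Per3 (−2.02, SE 0.320), Dbp (−1.54, SE 0.131), Ciart (−1.92, SE 0.236) and Cry2 (−0.99, SE 0.101) fell. Without day 7 library 2 or day 14 library 2, 2 clock genes rose and 5 fell, 2 rose without day 7 library 3 or day 14 library 1, and 6 fell without day 14 library 3.

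Of 20 muscarinic signalling and transport genes, 4 fell (5 when adjusted over the list alone), among them Itpr3 (−0.60, SE 0.102), Ano1 (−0.49, SE 0.102) and Prkcd (−0.33, SE 0.097). The number was 2 in each fit that left out a library of day 7 or day 14, and the median was −0.09 after the length correction. The muscarinic list had a median log2 change of −0.172 (camera adjusted p = 0.00163; adjusted p = 0.0961 with an estimated correlation). Dcpp1 rose from 23428 ± 288 to 34243 ± 2920 CPM (0.55, SE 0.109, adjusted p = 0.00636) and no longer passed after the length correction (0.38, adjusted p = 0.0834). The lipase gene Lpl of adipocytes and other cells rose (1.05, SE 0.116), alone of 7 adipocyte genes also when adjusted over the list alone (median 1.05, camera adjusted p = 0.0104; adjusted p = 0.514 with an estimated correlation). The list call ended without day 7 library 2 or day 14 library 3 (medians 0.236 to 2.458 over all omissions). Cfd (3.55, SE 1.77), Cidec (2.87, SE 1.52) and Car3 (2.83, SE 1.75) did not pass. Robo4 of the 18 endothelial genes fell (−0.90, SE 0.256; 1 also when adjusted over the list alone; median −0.215, camera adjusted p = 0.0345; adjusted p = 0.565 with an estimated correlation). The Robo4 call ended without day 7 library 1, 2 or 3 or day 14 library 1 or 2 (−1.09 to −0.76 over all omissions). The list call ended without day 7 library 2, day 14 library 1 or day 14 library 2 (medians −0.319 to −0.125). Notch3 of the 9 pericyte genes fell (−0.81, SE 0.190; 1 also when adjusted over the list alone; median −0.424, camera adjusted p = 0.0164; adjusted p = 0.319 with an estimated correlation). The Notch3 call ended without day 7 library 1 or 2 or day 14 library 2 (−0.91 to −0.63 over all omissions). This list call ended without day 7 library 1 or day 14 library 2 (medians −0.601 to −0.216). The plasma cell list passed with 0 of 14 genes called by edgeR, DESeq2 or limma-voom (3 with an unadjusted p under 0.05; median 0.938, camera adjusted p = 0.0292; adjusted p = 0.565 with an estimated correlation). The call ended without day 7 library 2, day 14 library 1 or day 14 library 2 (medians 0.542 to 1.33) and after the length correction (adjusted p = 0.0808).

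The other 17 lists did not pass from day 7 to day 14 (camera adjusted p 0.0553 to 0.956), except the unfolded protein response list without day 7 library 3 (adjusted p = 0.0186) or day 14 library 3 (0.00106). Their called members, other than Dcpp1, were named after their values were seen. Of 22 acinar genes Dcpp1, Dcpp2, Spdef and Cldn10 rose and Ano1 fell. The 4 acinar genes that rose became 1 without day 7 library 1 or 2 or day 14 library 1 or 2 and after the length correction, and 2 without control library 2, day 7 library 3 or day 14 library 3, and the Ano1 call was lost without day 14 library 1. Of 24 genes of the unfolded protein response Creld2, Manf, Calr and Sdf2l1 rose and Herpud1 fell. Of 20 ductal genes Klf5 and Scnn1a fell, and of 11 basal genes Itgb4 fell. Cnp rose among 15 Schwann cell genes, Mmp3 among 13 senescence genes and Jund among 17 immediate early genes. By edgeR 0 genes passed in the submandibular, neuronal, neurotrophic, lymphatic endothelial, matrix, skeletal muscle, erythrocyte, mitochondrially encoded, Wnt, epithelial progenitor, neutrophil, B cell and mast cell lists. At an unadjusted p under 0.05 there was 1 lower neuronal and 1 lower neurotrophic gene, 2 higher and 2 lower matrix, 1 lower skeletal muscle, 1 higher and 1 lower mitochondrially encoded, 2 higher and 1 lower Wnt, 2 epithelial progenitor and 1 B cell gene, and 0 in the rest. DESeq2 called 1 neuronal, 1 mitochondrially encoded, 1 Wnt and 1 epithelial progenitor gene. Limma-voom called 2 matrix, 2 mitochondrially encoded, 1 Wnt and 1 epithelial progenitor gene. Median, mean and test differed in sign for the neuronal (median 0.126, mean −0.629, test down), neurotrophic (0.036, 0.07, down), basal (0.017, −0.059, down), skeletal muscle (0.167, −0.048, down), unfolded protein response (0.176, −0.017, up), immediate early (0.008, −0.065, up) and epithelial progenitor (0.024, −0.019, down) lists.

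Key genes that did not pass between the times were Muc19 (0.12, SE 0.092), Aqp5 (0.10, SE 0.1), Bhlha15 (0.27, SE 0.095), Chrm1 (−0.31, SE 0.123), Chrm3 (−0.01, SE 0.093), Mdm2 (−0.31, SE 0.113), Krt19 (−0.13, SE 0.281), Krt5 (−0.08, SE 0.113), Tubb3 (−2.06, SE 1.84), Vip (−4.26, SE 1.43), Nrtn (0.24, SE 0.138), Sox2 (−0.15, SE 0.1), Sox10 (0.28, SE 0.097), Col1a1 (−0.26, SE 0.119), Adgre1 (0.58, SE 0.218) and Pecam1 (−0.09, SE 0.133). The number of called genes was 403, 330 and 636 without day 7 libraries 1, 2 and 3, and 410, 436 and 564 without day 14 libraries 1, 2 and 3. Of 70 named genes called, 34 passed with each library left out in turn. Of the 1011 genes, 1005 had no overlap between the groups' libraries, as did 29.4% of the genes tested, where chance gives 10%.

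Of the genes named above as called, Cldn10, Cox5a, Dcpp1, Dcpp2, Exo1, Ndufa4, Ndufs3, Prkcd, Rpl8, Rps23 and Xrcc6 no longer passed after the length correction (highest adjusted p = 0.226, for Dcpp2). The calls of Cldn10, Cnp, Dcpp2, Exo1, Jund, Ndufs3, Prkcd, Psrc1 and Xrcc6 ended in each fit that left out a library of day 7 or day 14, and those of Cldn10, Cnp, Cox5a, Dcpp2, Exo1, Ndufs3 and Prkcd also without control library 2. In all but 1 of these 6 fits the calls of Clock, Cox5a, Mmp3, Msh6 and Scnn1a ended, the exception being day 14 library 1 for Mmp3, day 14 library 3 for Cox5a and Msh6, day 7 library 1 for Clock and day 7 library 3 for Scnn1a. Of other genes, calls ended without day 7 library 1 for Isg15, Ndufa4, Ndufb8, Rps23, Rps3, Sdf2l1, Sesn2 and Spdef, without library 2 for Cd68, Herpud1, Isg15, Klf5, Ndufa4, Ndufb8, Nfil3, Per2, Per3, Sdf2l1 and Spdef and without library 3 for Klf5 and Nfil3. They ended without day 14 library 1 for Isg15, Klf5, Nfil3, Per3, Sdf2l1, Spdef and Zbp1, without library 2 for Ndufa4, Nfil3, Per2, Per3, Rps23, Sdf2l1, Sesn2 and Spdef and without library 3 for Herpud1, Isg15, Ndufa4, Ndufb8, Per2 and Per3 (highest adjusted p = 0.249 over all these fits, for Scnn1a). Of basal genes 2 fell without control library 1 or 3, and of the unfolded protein response 2 fell without control library 1. Of immediate early genes 2 rose without control library 1, 2 or 3, of adipocyte genes 2 without day 14 library 1, and of senescence genes 2 without control library 3 and after the length correction.

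A test of any difference among the 3 groups called 3893 genes, and 2542 without day 7 library 1. Of the genes called against control, 234 were called at both times with the same sign, 146 higher, Cdkn1a, Eda2r, Ephx1 and Ccng1 among them, and 88 lower, and 5 were called with opposite signs. The 234 became 13, 12 and 1752 without control libraries 1, 2 and 3, 122 without day 7 library 2, and 61, 22 and 27 without day 14 libraries 1, 2 and 3, and 114 after the length correction. Unchanged groups simulated with shared controls had too few calls to overlap (mean 0.067, at most 1 in 30 simulations), so they give no baseline for the 234. Independent lists of these sizes would share 27.3 higher and 14.4 lower genes. The log2 fold changes of the times correlated across genes (r = 0.609, 0.508 in the simulations) with a covariance of 0.203 (0.0623 in the simulations, a difference of 0.141), and 78.5% of genes had the same sign (66.9% in the simulations). The 3 controls are too few to split, so part of the excess may come from the controls common to both comparisons or from the trend with gene length.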

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

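The tests of collection time and of submandibular tissue in a control library were chosen only after their results were seen, as was the length and GC correction as an alternative, while the bounds for the tests of length and of other splits were set before their values were seen. The genes and lists in this paragraph stood out because their effects at the times differ, by the direct test of day 14 against day 7. That test called 1011 genes, 571 higher and 440 lower at day 14. By median log2 difference, day 14 minus day 7, lists that passed as higher were antigen presentation (1.109), T and NK cell (1.168), adipocyte (1.049), macrophage and monocyte (0.999), plasma cell (0.938), type I interferon (0.902), ribosomal protein (0.345) and oxidative phosphorylation (0.239). Lists that passed as lower were cell cycle (−1.739), clock (−0.835), pericyte (−0.424), DNA repair (−0.28), endothelial (−0.215), muscarinic (−0.172) and p53 targets (−0.171). Of these 15 list calls, the antigen presentation call alone held with an estimated correlation.

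For day 7 against control the real grouping of the 6 libraries called 4692 genes and was 1 of 10 splits with as many, the highest other split calling 0 by edgeR, the tool run on the splits (at an unadjusted p under 0.05 the other splits had 180 to 1423 genes and the real one 6296). For day 14 against control it called 270 genes, 1 of 10 splits, with at most 1 gene in another split, and for day 14 against day 7 1011 genes, 1 of 10 splits, again with at most 1 in another. With 10 splits these are too few for a share under 0.05. For a difference among the 3 groups the real grouping called 3893 genes, 1 of 100 splits with as many, and the highest other called 1076. That share argues against a random split of the libraries for that count, though only 100 of the possible splits were drawn.

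Ribosomal protein and oxidative phosphorylation genes were lower at day 7, with a median log2 change of −0.605 over 58 members. After a correction fitted outside both lists the median was −0.424 (−0.053 for all genes), with 47 members called lower against 52 before. This argues against a trend with exonic length as the whole cause, though the trend accounts for part of the size. The standard error of 0.034 ignores correlation between members (estimates 0.748 and 0.575). Irradiation and a difference in the cell types of the sections stay open, neither tested.

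Clock genes were displaced at day 7, and the list did not pass at day 14 against control (adjusted p = 0.468). A trend with gene length is argued against, since the median absolute log2 change of the 9 clock genes named was 2.198 before the length and GC correction and 2.217 after it, and of the whole list of 16, 9 rose and 3 fell before it and 10 and 4 after it. All 9 genes, which were picked after the displacement was seen, moved in antiphase directions with no overlap between day 7 and control libraries, as did 43.9% of all genes tested in either direction, which is consistent with glands collected at another time of day. An effect of irradiation on the clock would give the same values, so collection time and irradiation cannot be told apart in this design.

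The submandibular granular duct list passed as lower at both times against control, at neither with an estimated correlation (adjusted p = 0.698 and 0.552). Leaving out control library 3 moved the median at day 7 from −1.137 to −0.432 and at day 14 from −0.832 to 0.033. The list mean was −0.542, −0.71 and 1.25 in control libraries 1, 2 and 3. Chosen after its result was seen, the test leaves open more submandibular tissue in library 3. Also open and not tested is a fall with irradiation. The Klk1b members are near-identical copies, and reads assigned among them were not tested separately.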

How the results depend on the processing

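Of the named genes called, 85 of 120 at day 7, 4 of 36 at day 14 and 34 of 70 at day 14 against day 7 passed with each library left out in turn. Where a value moved the cause was not tested, except where a setting itself gives it (a stricter threshold, fewer libraries). The length and GC correction was chosen after seeing the data. The fit to only the 6 libraries compared was not run for a difference among all groups, since it needs 9. Depth limits genes near the floor of 0.154 to 0.188 CPM (Vip at day 14). By setting, the numbers of genes called at day 7, at day 14 and at day 14 against day 7 that moved by over 1.5 times were 2631, 11 and 264 with an adjusted p under 0.01 and 547, 35 and 212 with an absolute log2 change of at least 1 (4692, 270 and 1011 as reported). At day 14 they were 1300 with no filter, 1003 by DESeq2, 1678 by limma-voom, 157 with only the 6 libraries and 142 after the length correction, and limma-voom called 1874 at day 14 against day 7. The genes called at both times (234) became 1049 with no filter, 854 by DESeq2, 1451 by limma-voom, 125 with the 6 libraries and 114 after the length correction. DESeq2 gave no adjusted p to 27, 9 and 13 of the genes called by edgeR. With single libraries left out the counts ran from 3106 (without day 7 library 1) to 5314 (control library 3) at day 7, 13 (control library 1) to 1937 (control library 3) at day 14, 330 (day 7 library 2) to 1415 (control library 3) at day 14 against day 7, 2542 (day 7 library 1) to 4774 (control library 3) for any group and 12 (control library 2) to 1752 (control library 3) for both times. Lists called (12, 12 and 15) became 0, 0 and 1 by camera with an estimated correlation (6, 3 and 8 at an unadjusted p under 0.05) and 10, 1 and 10 by fry, while 34 of 39 list calls kept their side after the length correction and the basal list at day 7 and the antigen presentation and senescence lists at day 14 newly passed, none of the 3 with an estimated correlation (adjusted p = 0.543, 0.405 and 0.125). Of named gene results, 248 kept their direction and side of the threshold after the length correction, 66 no longer passed, 5 newly passed and 5 turned, and with DESeq2 290, 3, 30 and 1 did so.

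The replicate block is not backed by the labels or the data: same-numbered libraries deviated with correlations of −0.112 to 0.037, the others with −0.09 to 0.158, and 0 of 9 libraries correlated best with its own number. With the replicate block 4319, 113 and 746 genes were called, 3465 in any group and 95 at both times, Tubb3 at day 7 turned to 0.698, and no call of the 39 lists changed.

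None of the results below that turned had passed. After the length correction Krt5 (0.082) and Pecam1 (−0.011) turned at day 7, Chrm1 (−0.037) and Pecam1 (−0.018) at day 14 and Chrm3 (0.078) at day 14 against day 7. Chrm1 at day 14 turned with DESeq2 size factors (−0.014), without the 20 most abundant genes in the scaling (−0.012) and by DESeq2 (−0.012). With single libraries left out, at day 7 Chrm3 ran from −0.042 to 0.014, Tubb3 from −1.51 to 2.152, Vip from −1.464 to 0.756 and Adgre1 from −0.32 to 0.159. At day 14 Chrm1 ran from −0.146 to 0.088, Chrm3 from −0.062 to 0.008, Mdm2 from −0.129 to 0.008, Tubb3 from −4.901 to 0.078 and Pecam1 from −0.061 to 0.121. At day 14 against day 7 Chrm3 ran from −0.052 to 0.019, Krt19 from −0.398 to 0.153 and Car3 from −0.062 to 3.731.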

Other observations

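The lists and genes in this part were chosen after their values were seen, so each is a description of these libraries and not an independent test. Genes of sterol synthesis were higher at day 7, with 14 of 23 called higher and 2 called lower, a median log2 change of 0.659 (0.448 after the length and GC correction; camera adjusted p = 0.00034; adjusted p = 0.234 with an estimated correlation), and a median of 0.395 without day 7 library 1. Among them Idi1 rose by 1.68 (SE 0.299), Cyp51 by 0.91 (SE 0.157), Lss by 0.85 (SE 0.152) and the regulator Insig1 by 0.74 (SE 0.137), while Ebp fell by 0.52 (SE 0.109). From day 7 to day 14, 8 of the 23 fell (median −0.519, and −0.313 without day 7 library 1; adjusted p = 0.0721 with an estimated correlation). Genes of resident lymphocytes and dendritic cells were lower at day 7, with 6 of 13 called (median −1.252; camera adjusted p = 0.000808; adjusted p = 0.153 with an estimated correlation). The integrin Itgb7 fell by 2.08 (SE 0.394), Klrk1 by 2.43 (SE 0.631), Cxcr6 by 2.38 (SE 0.678), Itgae by 2.35 (SE 0.738), Ms4a4b by 1.97 (SE 0.663) and the dendritic cell receptor Xcr1 by 3.03 (SE 1.09), with control means from 0.789 (Xcr1) to 3.00 CPM (Itgb7). With libraries left out in turn, the Cxcr6 call ended without control library 1 (−1.98) or day 7 library 2 (−1.92), and the Itgae call without control library 2 (−1.78) or day 7 library 2 (−2.23) or 3 (−1.91). The Ms4a4b call ended without control library 1 (−1.69) or day 7 library 1 (−2.09) or 2 (−1.52). The Xcr1 call ended without control library 2 (−2.90) or 3 (−2.47), day 7 library 1 (−3.18), 2 (−2.49) or 3 (−3.69) or day 14 library 2 (−3.04). By day 14, 3 of the 13 had risen from day 7 (median 1.413; adjusted p = 0.072 with an estimated correlation).

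Targets of Atf4, a factor of amino acid stress, were lower at day 14 against control, with 4 of 31 called lower (median log2 −0.343, −0.344 after the length and GC correction; adjusted p = 0.0933 with an estimated correlation). Their mean lay at −0.437, −0.435 and −0.820 in the day 14 libraries, relative to the control mean. Without the 8 members that belong to a fixed list or had been seen before, 23 were left, 20 of them below 0 and 1 called lower, with a median of −0.29 (adjusted p = 0.274 with an estimated correlation). Adm2 (−0.97, SE 0.169), Sesn2 (−1.55, SE 0.261), Shmt2 (−0.54, SE 0.127) and Stc2 (−1.13, SE 0.281) fell in the fit to all libraries, of which Adm2, Sesn2 and Shmt2 no longer passed after the length correction (adjusted p = 0.0669, 0.062 and 0.0646). With libraries left out in turn, Adm2 no longer passed without control library 1 (−1.04) or 2 (−0.97) or day 14 library 3 (−0.79), and Sesn2 and Shmt2 each lost the call in 5 of the 9 omissions (over all omissions −1.83 to −1.37 and −0.69 to −0.43) and Stc2 in 8 (−1.46 to −0.90 over all omissions). Slc7a5 (−0.47, SE 0.119) and Pck2 (−0.51, SE 0.133) did not pass.

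The secretory genes Mucl2 and Prol1 differed widely between libraries of a group. Mucl2 lay at 4425, 7841 and 76404 CPM in control libraries 1, 2 and 3, at 1223, 1693 and 39.4 CPM at day 7 and at 200.4, 14195 and 1380 CPM at day 14. Prol1 lay at 469, 726 and 8369 CPM in the controls, at 135, 234 and 2.74 CPM at day 7 and at 5.78, 1724 and 177 CPM at day 14. Neither passed at day 7 by edgeR (Mucl2 −4.91, SE 2.28; Prol1 −4.68, SE 2.46), and both did by DESeq2 (adjusted p = 0.00528 and 0.0347).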
